A study of Mus musculus with 15 samples.

How the data were processed

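RAW264.7 cells, a mouse macrophage-like line, were profiled by RNA sequencing in 15 libraries: untreated cells and cells given 1 µg or 10 µg of the peptide LCCL for 6 h or 24 h, with 3 libraries per group. Per the labels, total RNA was extracted with TRIzol, purified on RNeasy columns and made into Illumina TruSeq stranded mRNA libraries. The authors deposited 1 table of whole-number read counts per gene symbol with 1 column per library. Their notes name the genome build GRCm39. The aligner, counting tool, annotation release, strand setting and any filter are not given in the sources used here. The table held 25639 symbols, of which 8141 had no count in any library. Symbols with a numbered suffix (44) were kept as separate genes. Each column was matched to its library by the column name in that library's label, and 0 columns were left unmatched. All libraries carry the same batch label, so batch could not be tested.

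Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr at its defaults, which left 12401 genes holding 99.97% of all counts. Libraries were scaled by TMM. All 15 libraries were fitted together with glmQLFit in its robust form, so that the 5 groups shared 1 estimate of the spread over 10 residual degrees of freedom, and contrasts were tested two-sided with glmQLFTest. The common biological coefficient of variation was 5.68% and the median prior degrees of freedom were 14.9. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change was its size over the square root of the F statistic. Fitted log2 fold changes used a prior count of 0.125. Levels are CPM, counts scaled to the TMM-adjusted library size.

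The 9 comparisons were each of the 4 treated groups with untreated cells, 10 µg with 1 µg at each time, 24 h with 6 h at each dose, and the interaction of dose and time. The labels name no vehicle group and give no harvest time for the untreated cells, so effects of time in culture may be contained in the comparisons with them. Library totals ran from 19085148 to 22434642 counts. A count of 0 was set against a floor of 3 counts, 0.13 to 0.16 CPM per library on the TMM-adjusted sizes, and folds against a group at 0 used 3 counts over the group. Where a group held 1 to 3 counts the ratio was given with an exact 95% Poisson interval.

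The genes named in the text follow a rule. For each comparison with untreated cells it takes the 8 called genes with the largest rise and the 8 with the largest fall that had at least 5 CPM in the higher group, all 3 libraries of one group on the same side of all 3 of the other, and a symbol other than a predicted-gene or clone name. For the other comparisons it takes 5 and 5, with no condition on single libraries for the interaction. It adds 16 core activation genes whatever they show (Nos2, Tnf, Il1b, Il6, Il12b, Cxcl10, Ptgs2, Acod1, Cd86, Cd40, Arg1, Mrc1, Retnla, Chil3, Il10 and Il1rn) and up to 4 members of each gene list with the smallest p. Exceptions say so.

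Gene lists numbered 48, written from textbook knowledge, and 121 genes were in more than 1 list. They were M1 (classical activation) markers, M2 (alternative activation) markers, pro-inflammatory cytokines, chemokines, NF-kB feedback and target genes, interferon-stimulated genes, negative regulators of TLR and cytokine signalling, immediate early genes, pattern recognition receptors and adaptors, inflammasome and pyroptosis genes, MHC class II antigen presentation and MHC class I antigen processing. Further lists were co-stimulatory and checkpoint ligands, homeostatic macrophage genes, phagocytic and Fc receptors, osteoclast differentiation genes, glycolysis, TCA cycle, nuclear oxidative phosphorylation, mitochondrially encoded transcripts, pentose phosphate pathway, cholesterol biosynthesis and uptake, LXR targets and cholesterol efflux, fatty acid synthesis and storage, eicosanoid synthesis, NRF2 targets, hypoxia targets, unfolded protein response, ATF4 amino acid response, heat shock genes and lysosome and autophagy genes. The rest were DNA replication, mitosis, p53 targets, apoptosis and survival genes, ribosome biogenesis, cytosolic ribosomal proteins, matrix proteases and inhibitors, complement and coagulation genes, iron and metal handling, Toll-like receptor primary and secondary response genes, and markers of fibroblasts, epithelium, T cells, B cells, neutrophils and dendritic cells. The 43 lists with at least 5 tested members were tested two-sided with camera (limma 3.58.1, preset correlation 0.01, prior count 2), which compares a list with all other tested genes, and p-values were adjusted over the lists within a comparison. The same test was run with the correlation estimated for each list. The rotation test fry was also run; its p-value asks if a list's genes move on balance one way and does not compare them with other genes. For each list the called members were counted with p-values adjusted over all genes and adjusted over the list alone.

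The test, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The alternatives were DESeq2's size factors in edgeR, library totals without composition scaling, no filter, a filter at a mean of 5 CPM, counts thinned to the smallest library, the replicate number as a block, only the groups compared, each replicate left out in turn, DESeq2 1.42.0 with its own test, limma-voom, and for lists the estimated correlation and fry. The procedure was tested on counts drawn from a negative binomial at the untreated means, with changes put into the 1 µg 6 h group, over 12022 genes. With 50 genes at each size it recovered 66% of those changed by 0.322 on the log2 scale, 82% at 1.5-fold, 100% at 2-fold and 98% at 4-fold, with 0 wrong signs. It called 6 of 11792 unchanged genes, found a moved list of 30 genes and called 0 of 40 unmoved lists. The simulated genes were drawn independently of each other, so these list results do not cover lists whose genes are correlated. Overlap of exons between genes was taken from a reference mouse annotation on an earlier build, by symbol and without coordinates, and overlapping genes are reported as uncertain. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.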

Results

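RNA was sequenced from RAW264.7 cells, a mouse macrophage-like line, that were left untreated or exposed to LCCL, a peptide built around an LCCL core motif. The series title presents the peptide as a potential drug that differentiates M1 macrophages, which are the classically activated, inflammatory form of the cell. The 15 libraries made 5 groups of 3: untreated, 1 µg LCCL for 6 h, 1 µg for 24 h, 10 µg for 6 h and 10 µg for 24 h. The labels give the doses without a volume, name 1 batch, include no vehicle control and give no harvest time for the untreated cells. Library totals ran from 19085148 to 22434642 counts, and 12401 genes were tested. Each group had n = 3 libraries throughout. Levels are means of CPM, counts scaled to library size, ± SD, and changes are log2 fold changes ± SE with p-values from edgeR's quasi-likelihood test adjusted by the Benjamini-Hochberg method. A gene is said to rise or fall where its adjusted p was under 0.05. The p-values measure only the spread between these libraries, which may be technical, and counting intervals and floors cover counting error alone.

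The comparison of 1 µg for 6 h with untreated cells asked how cells differed early at the lower dose. Tnf, the gene of an inflammatory cytokine, stood at 115 ± 2.58 CPM against 100.1 ± 1.01 CPM, a log2 fold change of 0.20 ± 0.14 that did not pass (adjusted p = 1). Acod1, whose enzyme makes itaconate, gave 0.41 ± 0.30, the interferon-induced chemokine gene Cxcl10 gave 0.19 ± 0.12, the co-stimulatory receptor gene Cd40 gave 0.30 ± 0.26 and the interleukin antagonist gene Il1rn gave 0.04 ± 0.16. Ptgs2, the inducible cyclooxygenase gene, gave 0.01 ± 0.40, Cd86 gave -0.34 ± 0.47, Mrc1 gave -0.36 ± 0.32 and Arg1 gave -0.52 ± 0.37, and Nos2, the inducible nitric oxide synthase gene, had 2 counts against 5. By edgeR 0 of 12401 genes passed, 337 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Without a filter on low counts 1 gene passed, Ankrd23, named after its values were seen, with 44 counts in this group and 0 in every other group.

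Small shifts shared by whole gene lists were tested at 1 µg and 6 h with camera, which compares a list with all other genes. The 26 tested NF-kB feedback and target genes had a median log2 fold change of 0.07 (camera adjusted p = 5.22e-05) and the 16 Toll-like receptor primary response genes a median of 0.10 (camera adjusted p = 0.00128). Medians were -0.04 for 47 DNA replication genes, -0.03 for 51 mitosis genes and -0.04 for 63 oxidative phosphorylation genes, with camera adjusted p = 0.0077, 0.0077 and 0.0164. No member of any list passed over all genes or adjusted over the list alone, and each of the 5 lists had adjusted p = 0.977 with an estimated correlation. Only the NF-kB list stayed past the threshold without each of the 6 libraries in turn. The replication list had adjusted p = 0.146, 0.0994 and 0.0697 without 1 µg 6 h replicate 2, 1 µg 6 h replicate 3 and untreated replicate 2. The mitosis list had 0.184 and 0.154 without 1 µg 6 h replicate 2 and untreated replicate 2. The oxidative phosphorylation list had 0.216, 0.197, 0.208 and 0.0521 without 1 µg 6 h replicates 2 and 3 and untreated replicates 1 and 2, and the primary response list had 0.0697 without untreated replicate 2.

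The comparison of 10 µg for 6 h with untreated cells asked how cells differed early at the higher dose, and inflammatory response genes rose. Acod1 rose from 11.6 ± 1.21 to 43.7 ± 3.5 CPM (1.91 ± 0.28, adjusted p = 0.00261), and Tnf rose from 100.1 ± 1.01 to 195 ± 1.49 CPM (0.96 ± 0.14, adjusted p = 0.00204). Hal, which encodes the first enzyme of histidine breakdown, rose by 1.19 ± 0.12 (adjusted p = 6.83e-07) and Gpr84, a receptor for medium-chain fatty acids, by 0.92 ± 0.09 (adjusted p = 4.31e-06). Pmepa1, a transcript induced by TGF-beta, went from 54.6 ± 3.25 to 113 ± 6.13 CPM (1.05 ± 0.10, adjusted p = 3.36e-06). Rgs16, a brake on G-protein signalling, rose by 1.14 ± 0.16 and the serine protease gene Prss46 by 1.02 ± 0.15. The zinc finger gene Zfp608 fell by 0.65 ± 0.12 on the log2 scale (adjusted p = 0.000882) and the lectin gene Clec4a3 by 0.64 ± 0.11 (adjusted p = 0.00046).

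In all, 738 genes (5.95%) passed at 10 µg and 6 h, 507 higher and 231 lower, of which 16 rose and 4 fell by at least 2-fold. The median size of the called changes was 0.286 on the log2 scale. When only the 2 groups compared were fitted the count was 1487. It fell to 400, 469 and 433 without untreated replicates 1, 2 and 3, and to 458, 390 and 445 without 10 µg 6 h replicates 1, 2 and 3.

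Of the 16 core activation genes fixed in advance, 5 rose at 10 µg and 6 h. Beside Tnf and Acod1 these were Cxcl10 (17.8 ± 0.581 against 12.6 ± 0.186 CPM, 0.50 ± 0.12, adjusted p = 0.0105), whose exons overlap those of Art3 on the other strand. Also up were Cd40 (0.96 ± 0.24, adjusted p = 0.0151) and Il1rn (0.63 ± 0.16, adjusted p = 0.0413). Il1rn did not pass without any 1 of the 6 libraries (adjusted p from 0.0918 to 0.128), nor did the neutrophil chemokine gene Cxcl2 (1.68 ± 0.41, adjusted p = 0.0399, from 0.099 to 0.132). Without a filter on low counts both missed as well (0.0531 and 0.051), and Il1rn also with the replicate block (0.0524). Cd40 did not pass without untreated replicate 1 (0.0992) or 10 µg 6 h replicate 1 (0.0826), and Cxcl10 not without 10 µg 6 h replicate 2 (0.0589). Over all alternatives adjusted p ran from 1.07e-11 to 0.128 for Il1rn, from 2.47e-11 to 0.132 for Cxcl2, from 0.00222 to 0.0992 for Cd40 and from 0.000155 to 0.0589 for Cxcl10. Ptgs2 did not pass (0.62 ± 0.39, adjusted p = 0.461), but did when only the 2 groups were fitted (4.72e-05, range over alternatives 4.72e-05 to 0.616). Nos2 had 7 counts against 5 (0.47 ± 0.97), and Cd86 (0.33 ± 0.42) and the alternative-activation genes Arg1 (0.77 ± 0.32, adjusted p = 0.183) and Mrc1 (-0.52 ± 0.32) did not pass.

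Falls at 10 µg and 6 h were ranked among called genes with at least 5 CPM, libraries that separated the groups and a symbol other than a predicted-gene or clone name. Besides Zfp608 and Clec4a3, the 8 largest of these held Sys1 (-0.70 ± 0.16), a Golgi trafficking gene whose exons overlap Gm20458 on the same strand, Nphs1 (-0.70 ± 0.20) and the fucosyltransferase gene Fut7 (-0.67 ± 0.15). The rest were the aryl hydrocarbon receptor repressor Ahrr (-0.62 ± 0.17), Eml6 (-0.61 ± 0.14), which overlaps Rtn4 on the other strand, and the immune receptor gene Cd300e (-0.56 ± 0.14). These 6 did not hold in every alternative. Nphs1 had adjusted p = 0.143 and 0.12 without untreated replicates 1 and 2 and 0.0993, 0.135 and 0.113 without 10 µg 6 h replicates 1, 2 and 3, and 0.0647 with limma-voom. Ahrr had 0.118 and 0.0998 without untreated replicates 2 and 3 and 0.183 and 0.134 without 10 µg 6 h replicates 1 and 2. Cd300e had 0.0569 and 0.0579 without untreated replicates 1 and 3 and 0.0531 and 0.0652 without 10 µg 6 h replicates 1 and 2. Sys1 had 0.0536 without untreated replicate 1 and 0.071 and 0.0692 without 10 µg 6 h replicates 2 and 3. Fut7 had 0.0899 without untreated replicate 3 and 0.0626 without 10 µg 6 h replicate 3, and Eml6 had 0.0612 without 10 µg 6 h replicate 3.

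**Figure D1:**
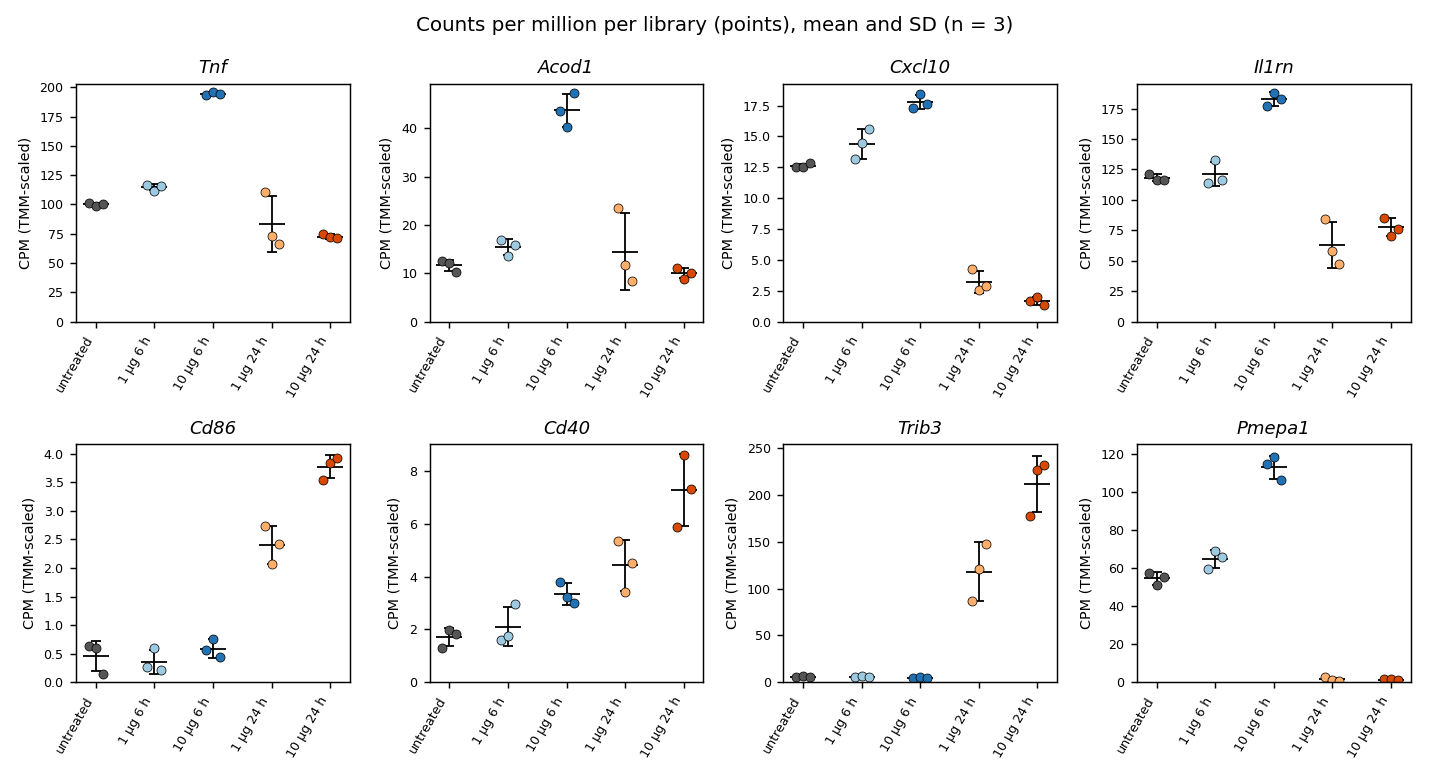
CPM (TMM-scaled, linear axes from 0) of Tnf, Acod1, Cxcl10, Il1rn, Cd86, Cd40, Trib3 and Pmepa1 in the 5 groups, with 1 point per library and bars for the mean and SD (n = 3). Tnf reached 195 CPM at 10 µg and 6 h against 100.1 CPM untreated, Trib3 reached 212 CPM at 10 µg and 24 h, and Pmepa1 stood at 1.61 and 1.42 CPM at 24 h.

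Lists of inflammatory genes moved together at 10 µg and 6 h. Of 26 NF-kB feedback and target genes, 18 rose and 0 fell (21 rose adjusted over the list alone), with a median of 0.38 and camera adjusted p = 2.28e-20. The NF-kB genes that rose included Tnfaip3 (0.79 ± 0.07), Nfkbiz (0.80 ± 0.08), Nfkbie (0.59 ± 0.07) and Zc3h12a (0.65 ± 0.08). Of 13 Toll-like receptor secondary response genes, 7 rose (9 adjusted over the list alone, median 0.47, camera adjusted p = 5.94e-07), including Ptges (0.79 ± 0.13), Rsad2 (0.44 ± 0.09) and Ifit1 (0.42 ± 0.09). With an estimated correlation these 2 lists kept their calls (adjusted p = 0.0141 and 0.0209), and of all 9 comparisons only these lists, here and between the doses at 6 h, did so. Of 16 primary response genes 10 rose (13 adjusted over the list alone, median 0.46, camera adjusted p = 6.11e-13), with adjusted p = 0.241 with an estimated correlation. Icam1 gave 0.29 ± 0.05 and Nfkbia gave 0.26 ± 0.05. Of 43 interferon-stimulated genes 23 rose and 0 fell (29 adjusted over the list alone, median 0.28, camera adjusted p = 4.93e-17), and the list had adjusted p = 0.203 with an estimated correlation. Among them were Usp18 (0.51 ± 0.06), Mx2 (0.73 ± 0.09), Slfn5 (0.36 ± 0.05) and Stat2 (0.31 ± 0.05). Of 22 negative regulators of these pathways 9 rose (9 adjusted over the list alone, camera adjusted p = 0.000225), with adjusted p = 0.299 with an estimated correlation. Tnip1 (0.39 ± 0.06) and Dusp4 (0.30 ± 0.05) were among these. Among 13 co-stimulatory and checkpoint ligands 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00467), with adjusted p = 0.289 with an estimated correlation. Cd83 (0.62 ± 0.06) and Cd274 (0.67 ± 0.14) were up. Among 18 osteoclast differentiation genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000188), with adjusted p = 0.112 with an estimated correlation. Nfatc1 (0.58 ± 0.06) and Src (0.65 ± 0.07) rose.

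The M1 and M2 marker lists gave less. Of 13 tested M1 markers 4 rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone (median 0.37, camera adjusted p = 0.0224). The M1 list had adjusted p = 0.329 with an estimated correlation, 0.0628 without untreated replicate 3 and 0.0638 without 10 µg 6 h replicate 3. Of 13 tested M2 markers 1 rose (Tgm2, 0.54 ± 0.14) and 2 fell (Clec7a, -0.45 ± 0.06, and Clec10a, -0.55 ± 0.15), 2 and 2 adjusted over the list alone. Tgm2 missed without untreated replicates 1 and 3 (0.101 and 0.107) and without 10 µg 6 h replicates 1, 2 and 3 (0.0516, 0.0662 and 0.0979). Clec10a missed without untreated replicates 1 and 3 (0.0949 and 0.112), without 10 µg 6 h replicates 1 and 3 (0.0834 and 0.0865) and with limma-voom (0.0508). The median of 0.22 and the test's downward direction differed in sign (camera adjusted p = 0.916). Of 9 chemokine genes 3 rose (5 adjusted over the list alone, camera adjusted p = 0.0193), with adjusted p = 0.329 with an estimated correlation. Ccl4 (0.47 ± 0.10) was 1 of them. Of 10 cytokine genes 2 rose, Tnf and Tnfsf9 (0.28 ± 0.06), and 3 adjusted over the list alone (camera adjusted p = 0.0268). The cytokine list had adjusted p = 0.289 with an estimated correlation, 0.0811 without untreated replicate 1 and 0.156 without 10 µg 6 h replicate 3. Tnfsf9 missed without untreated replicate 2 (0.0523) and 10 µg 6 h replicate 2 (0.0589).

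Further lists passed at 10 µg and 6 h with smaller shifts. Of 51 mitosis genes 13 fell (26 adjusted over the list alone, median -0.15, camera adjusted p = 1.92e-12), such as Ube2c (-0.25 ± 0.05) and Kif11 (-0.27 ± 0.06, and 0.0719 as adjusted p without untreated replicate 2), with adjusted p = 0.289 with an estimated correlation. Of 47 DNA replication genes 3 fell (11 adjusted over the list alone, median -0.13, camera adjusted p = 1.18e-06), with adjusted p = 0.466 with an estimated correlation. Of 24 cholesterol synthesis genes 11 rose (13 adjusted over the list alone, camera adjusted p = 1.74e-07), such as Insig1 (0.36 ± 0.06) and Hmgcs1 (0.25 ± 0.05), with adjusted p = 0.289 with an estimated correlation. Of 63 oxidative phosphorylation genes 1 fell (0 adjusted over the list alone, median -0.07, camera adjusted p = 0.0018), with adjusted p = 0.289 with an estimated correlation. Calls of 6 more lists ended without single libraries and had adjusted p from 0.289 to 0.448 with an estimated correlation. The matrix protease list (5 of 17 rose, 7 adjusted over the list alone, Plau 0.71 ± 0.09) went from 0.0212 to 0.0517 and the immediate early list (5 of 22 rose, 10 adjusted over the list alone) from 0.00435 to 0.0517, each without untreated replicate 2. The pentose phosphate list (1 of 10 fell, 1 adjusted over the list alone) went from 0.0299 to 0.129 without untreated replicate 1. The pattern recognition list (5 of 33 rose and 2 fell, 6 and 3 adjusted over the list alone) went from 0.0486 to 0.0517 and 0.0771 without untreated replicates 2 and 3 and to 0.224 without 10 µg 6 h replicate 1. The LXR target list (1 of 12 rose, 2 adjusted over the list alone) went from 0.0486 to 0.108 and 0.0517 without untreated replicates 1 and 2 and to 0.111 without 10 µg 6 h replicate 3. The fatty acid list (2 of 19 rose, 2 adjusted over the list alone) went from 0.0486 to 0.0694, 0.0806 and 0.15 without untreated replicates 1 and 2 and 10 µg 6 h replicate 1. With the replicate block the pattern recognition, LXR and fatty acid lists had 0.0561, 0.0526 and 0.0561.

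The comparison of 10 µg with 1 µg at 6 h tested the early dose difference directly. Acod1 was 2.83-fold higher at 10 µg (43.7 ± 3.5 against 15.5 ± 1.67 CPM, adjusted p = 0.0199). Hal was higher by 1.12 ± 0.12 (adjusted p = 4.44e-06), Rgs16 by 0.94 ± 0.16 (adjusted p = 0.00152), Pmepa1 by 0.80 ± 0.09 (adjusted p = 0.000138) and Tnf by 0.76 ± 0.14 (adjusted p = 0.0171). Acod1 and Tnf did not pass without any 1 of the 6 libraries, with adjusted p from 0.0571 to 0.0984 and from 0.0554 to 0.0812, and ran from 9.55e-13 to 0.0984 and from 2.26e-14 to 0.0812 over all alternatives. Pmaip1, a pro-apoptotic gene, was lower (-0.47 ± 0.09, adjusted p = 0.00213), as were Clec4a3 (-0.51 ± 0.11), Arrdc3 (-0.47 ± 0.12), Gpr85 (-0.47 ± 0.12) and Rgs18 (-0.41 ± 0.10). Of these, Clec4a3 had adjusted p = 0.0752 and 0.0898 without 1 µg 6 h replicates 1 and 2 and 0.0698 without 10 µg 6 h replicate 2. Arrdc3 had 0.169 and 0.112 without 1 µg 6 h replicates 2 and 3 and 0.107 and 0.19 without 10 µg 6 h replicates 2 and 3. Gpr85 had 0.167, 0.129 and 0.0744 without 1 µg 6 h replicates 1, 2 and 3 and 0.169 and 0.193 without 10 µg 6 h replicates 2 and 3, and 0.0525 with the replicate block and 0.0658 with limma-voom. Rgs18 had 0.169 and 0.114 without 1 µg 6 h replicates 1 and 2 and 0.0537, 0.122 and 0.148 without 10 µg 6 h replicates 1, 2 and 3. It also missed with limma-voom (0.0891) and with counts thinned to the smallest library (0.0592).

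Between the doses at 6 h 291 genes passed, 230 higher and 61 lower at 10 µg. The count was 1044 when only these 2 groups were fitted, 123, 138 and 145 without 1 µg 6 h replicates 1, 2 and 3, and 163, 111 and 135 without 10 µg 6 h replicates 1, 2 and 3. Of the NF-kB genes 12 of 26 were higher (19 adjusted over the list alone, camera adjusted p = 1.45e-19, adjusted p = 0.0164 with an estimated correlation). Of the secondary response genes 2 of 13 were higher (8 adjusted over the list alone, camera adjusted p = 5.14e-06, adjusted p = 0.0359 with an estimated correlation). Of the interferon-stimulated genes 17 of 43 were higher (31 adjusted over the list alone, camera adjusted p = 2.56e-19, adjusted p = 0.148 with an estimated correlation). Of the primary response genes 6 of 16 were higher (12 adjusted over the list alone, camera adjusted p = 2.49e-11, adjusted p = 0.23 with an estimated correlation). In all 19 of 43 tested lists passed with the preset correlation.

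The comparison of 1 µg for 24 h with untreated cells asked how cells differed late at the lower dose. Here and in the other comparisons with untreated cells, effects of the peptide and of time in culture cannot be told apart by the comparison alone. Trib3, a pseudokinase gene induced by the stress factor ATF4, rose from 5.85 ± 0.681 to 118 ± 31 CPM (4.33 ± 0.24, adjusted p = 2.92e-08). Soat2, which esterifies cholesterol, rose from 4.53 to 65.1 ± 9.92 CPM (3.84 ± 0.10, adjusted p = 2.23e-19), and the stress cytokine gene Gdf15 rose by 3.58 ± 0.20 (adjusted p = 1.27e-13). The mitochondrial folate enzyme Aldh1l2 (3.39 ± 0.20), the cysteine-producing enzyme Cth (3.36 ± 0.21), Glrp1 (3.42 ± 0.15) and Zrsr1 (4.48 ± 0.68), which overlaps Commd1 on the other strand, also rose. Pmepa1 fell from 54.6 to 1.61 CPM (-5.06 ± 0.16, adjusted p = 6.26e-14), and the Id genes, whose products hold back helix-loop-helix factors, fell with it: Id1 gave -3.32 ± 0.13, Id2 gave -2.77 ± 0.06 and Id3 gave -3.03 ± 0.12. Gadd45g (-3.19 ± 0.18) and Yy2 (-3.50 ± 0.46) fell too. Exosc6 went from 1834 counts to 0, at least 646.2-fold lower against a floor of 3 counts over the group, and its exons overlap those of Aars on the same strand, as those of Yy2 overlap Mbtps2.

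In all, 7658 genes (61.8%) passed at 1 µg and 24 h, 3817 higher and 3841 lower, of which 718 rose and 188 fell by at least 2-fold. The median size of the called changes was 0.421 on the log2 scale. With library totals alone in place of TMM scaling, the median log2 fold change of all genes shifted by 0.102 and the split was 4923 higher and 2864 lower (63.22% higher against 49.84%). By the mean squared difference between libraries over that from counting error, 1 µg 24 h replicate 1 stood apart from its group. This was 13.3 and 15.03 for its pairs with replicates 2 and 3 and 5.627 between those. On the first principal component, the main axis of difference between libraries, replicate 3 stood apart instead. It lay at 38.36 against 29.53 and 29.08 for replicates 1 and 2.

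Among the core activation genes at 1 µg and 24 h, Cd86, a co-stimulatory ligand gene, rose from 0.459 ± 0.269 to 2.41 ± 0.333 CPM (2.36 ± 0.34, adjusted p = 1.57e-06). Cd40 rose by 1.37 ± 0.23 (adjusted p = 1.6e-05) and the mannose receptor gene Mrc1 by 1.32 ± 0.27 (adjusted p = 0.000161). Cxcl10 fell from 12.6 ± 0.186 to 3.23 ± 0.886 CPM (-1.96 ± 0.14, adjusted p = 1.17e-11) and Il1rn fell as well (-0.91 ± 0.16, adjusted p = 0.000588). Tnf (-0.26 ± 0.14, adjusted p = 0.136) and Ptgs2 (-0.53 ± 0.41, adjusted p = 0.285) did not pass, but did without 1 µg 24 h replicate 1, at -0.52 (adjusted p = 4.85e-10) and -1.46 (adjusted p = 3.29e-09), and with limma-voom (adjusted p = 0.0245 and 0.019). Their ranges of adjusted p over all alternatives were 4.85e-10 to 0.402 and 3.29e-09 to 0.662. Acod1 (0.33 ± 0.30), Nos2 (1.23 ± 0.86) and Arg1 did not pass.

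The comparison of 10 µg for 24 h with untreated cells asked how cells differed late at the higher dose. Trib3 reached 212 ± 30 CPM (5.18 ± 0.23, adjusted p = 2.68e-09) and Gdf15 reached 14.7 ± 1.21 CPM (5.02 ± 0.18, adjusted p = 1.39e-17). Cp, which encodes the copper-carrying ferroxidase ceruloplasmin and overlaps Hps3 on the other strand, rose by 5.85 ± 0.43, the integrin gene Itgad by 5.39 ± 0.45, the matrix gene Fbln5 by 5.05 ± 0.38, Extl1 by 5.97 ± 0.32 and Zrsr1 by 4.83 ± 0.67. Cox6a2, a cytochrome oxidase subunit gene whose exons overlap those of Itgad on the other strand, went from 2 to 530 counts, a ratio of 270.4 (95% counting interval 74.48 to 2239), and both untreated counts lay in untreated replicate 1. Pmepa1 fell to 1.42 ± 0.14 CPM (-5.26 ± 0.16, adjusted p = 1.34e-14), and Id1 (-4.20 ± 0.14) and Id3 (-4.02 ± 0.13) fell, and so did the endocytic scaffold gene Itsn1 (-6.35 ± 0.65, adjusted p = 4.58e-06) and Ube2v1 (-4.65 ± 1.05, adjusted p = 0.00227), which overlaps Gm20431 on the same strand. Their falls were larger without 10 µg 24 h replicate 2 for Itsn1 (-8.13) and replicate 1 for Ube2v1 (-5.40). Id2, named here after its values were seen, fell less far at 10 µg than at 1 µg, to 43.3 against 21 CPM (adjusted p = 2.66e-12 between the doses). Exosc6 and Yy2 were at 0 counts, at least 599.1-fold and 112.7-fold lower against a floor of 3 counts over the group.

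In all, 8717 genes (70.3%) passed at 10 µg and 24 h, 4388 higher and 4329 lower, of which 1126 rose and 639 fell by at least 2-fold. The median size of the called changes was 0.536 on the log2 scale. With library totals alone the split was 5112 higher and 3600 lower (58.68% higher against 50.34%). Among the core genes, Cd86 rose to 3.77 ± 0.201 CPM (3.01 ± 0.33, adjusted p = 9.72e-09), Cd40 to 7.28 ± 1.37 CPM (2.09 ± 0.22, adjusted p = 8.39e-09) and Mrc1 by 0.94 ± 0.28 (adjusted p = 0.00434). Nos2 rose from 5 to 41 counts over the group, or 0.0816 to 0.67 CPM (2.97 ± 0.70, adjusted p = 0.000522), a low level beside the 72.6 CPM of Tnf. Without untreated replicate 1 the ratio for Nos2 was 2.88 times as high. Tnf fell by 0.46 ± 0.14 on the log2 scale (adjusted p = 0.0136), Cxcl10 by 2.90 ± 0.16 (adjusted p = 1.87e-14) and Il1rn by 0.61 ± 0.16 (adjusted p = 0.00589). Ptgs2 passed (-1.20 ± 0.44, adjusted p = 0.0306), but had 0.057, 0.0602 and 0.0609 without untreated replicates 1, 2 and 3 and 0.0732 and 0.0927 without 10 µg 24 h replicates 2 and 3 (1.32e-07 to 0.0927 over all alternatives). Acod1 (-0.22 ± 0.32) and Arg1 (-0.68 ± 0.37) did not pass. The other core genes held too few counts to pass the filter and no test is given for them. Il1b had 34 counts over all 15 libraries, Il6 had 5 and Il10 had 54, and Il12b, Retnla and Chil3 had 0. The Il10 counts over the group were 20 untreated, 23 at 1 µg 6 h and 9 at 10 µg 6 h. They were 2 at 1 µg 24 h and 0 at 10 µg 24 h.

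Genes of cell division and ribosome production fell at 24 h with both doses. All 47 tested DNA replication genes fell at 1 µg (47 adjusted over the list alone, median -0.77, camera adjusted p = 2.03e-17, adjusted p = 0.223 with an estimated correlation) and at 10 µg (47 again, median -1.46, camera adjusted p = 6.23e-19, adjusted p = 0.233 with an estimated correlation). Mcm3, part of the helicase that opens DNA, gave -1.09 ± 0.06 and -1.79 ± 0.06, and Rpa1 gave -0.91 ± 0.05 and -1.44 ± 0.05. Of 51 mitosis genes 49 fell at 1 µg (median -0.46, camera adjusted p = 1.75e-12, adjusted p = 0.293 with an estimated correlation) and 51 at 10 µg (median -0.91, camera adjusted p = 7.65e-17, adjusted p = 0.233 with an estimated correlation), with the same counts adjusted over the list alone. The cell cycle kinase genes Cdk1 (-0.90 ± 0.06 and -1.42 ± 0.07) and Aurkb (-0.65 ± 0.05 and -1.25 ± 0.05) were among them. Of 37 ribosome biogenesis genes 34 fell and 1 rose at 1 µg (median -0.63, camera adjusted p = 1.75e-12, adjusted p = 0.223 with an estimated correlation) and 35 fell and 1 rose at 10 µg (median -0.80, camera adjusted p = 1.91e-11, adjusted p = 0.233 with an estimated correlation), the same adjusted over the list alone. Dkc1 gave -1.03 ± 0.05 and -1.53 ± 0.05. Cytosolic ribosomal protein genes were mixed, with 8 of 75 higher and 20 lower at 1 µg (7 and 16 adjusted over the list alone, camera adjusted p = 0.451) and 7 and 22 at 10 µg (6 and 18 adjusted over the list alone, camera adjusted p = 0.153).

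Stress pathways divided at 24 h. Of 22 ATF4 amino acid response genes 20 rose at 1 µg and 19 at 10 µg with 0 falling (the same adjusted over the list alone, camera adjusted p = 6.16e-11 and 1.05e-08, with adjusted p = 0.223 and 0.233 with an estimated correlation). Sesn2 gave 2.41 ± 0.07 and 2.79 ± 0.07, Chac1 gave 2.76 ± 0.10 and 3.01 ± 0.10, and Atf4 itself 1.07 ± 0.06 and 1.33 ± 0.06. Of 14 heat shock genes 12 fell and 1 rose at each dose (the same adjusted over the list alone, medians -0.67 and -0.78, camera adjusted p = 6.75e-05 and 0.000497, with adjusted p = 0.223 and 0.233 with an estimated correlation). The chaperone gene Hspa8 gave -1.09 ± 0.05 and -1.28 ± 0.05. Of 20 NRF2 targets 16 fell and 1 rose at 1 µg and 15 fell and 3 rose at 10 µg (the same adjusted over the list alone, camera adjusted p = 0.000112 and 0.00868, with adjusted p = 0.429 and 0.641 with an estimated correlation). Gclc, needed to make glutathione, gave -1.01 ± 0.07 and -1.38 ± 0.08, and Sqstm1 gave 1.16 ± 0.07 at 10 µg. Of 23 p53 targets 14 rose and 4 fell at 1 µg (camera adjusted p = 0.0076, adjusted p = 0.501 with an estimated correlation) and 10 and 6 at 10 µg (camera adjusted p = 0.263). Bbc3 gave 1.84 ± 0.11 and 2.31 ± 0.10. Of 25 hypoxia targets 15 rose and 3 fell at 1 µg, 16 and 5 adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.45 with an estimated correlation), and 16 and 7 at 10 µg (camera adjusted p = 0.0689). Vegfa gave 2.16 ± 0.07 and 2.47 ± 0.07. In the unfolded protein response list 5 of 21 rose and 11 fell at 1 µg and 7 and 12 at 10 µg (camera adjusted p = 0.221 and 0.342). At 1 µg that list had 0.0194 without 1 µg 24 h replicate 1. Apoptosis and survival genes went both ways, 7 of 22 up and 8 down at 1 µg, where the median of -0.04 and the mean of 0.02 differed in sign, and 9 and 9 at 10 µg (camera adjusted p = 0.937 and 0.883).

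Genes of sterol and lipid handling also divided at 24 h. Of 12 genes in the list of LXR targets and cholesterol efflux, 9 rose and 1 fell at 1 µg and 10 and 1 at 10 µg (the same adjusted over the list alone, medians 0.69 and 0.81, camera adjusted p = 0.000112 and 0.00065, with adjusted p = 0.223 and 0.233 with an estimated correlation). The transporter genes Abca1 (3.29 ± 0.10 and 3.88 ± 0.10) and Abcg1 (2.18 ± 0.06 and 2.40 ± 0.06) led the list. Of 24 cholesterol synthesis genes 10 fell and 3 rose at 1 µg (camera adjusted p = 0.0804) and 13 fell and 2 rose at 10 µg (camera adjusted p = 0.0353, adjusted p = 0.735 with an estimated correlation). Hsd17b7 gave -1.03 ± 0.06 and -1.26 ± 0.06. This list had 0.0412 and 0.0312 at 1 µg without 1 µg 24 h replicates 1 and 2, and at 10 µg 0.053 without untreated replicate 3 and 0.0618 with library totals alone. The fatty acid list had 7 of 19 up and 5 down at 1 µg and 9 and 9 at 10 µg, where the median of -0.07 and the mean of 0.11 differed in sign (camera adjusted p = 0.463 and 0.808). Scd1 gave 1.51 ± 0.07 and 1.35 ± 0.07. In the eicosanoid synthesis list 5 of 14 rose and 2 fell at 1 µg and 5 and 7 at 10 µg (camera adjusted p = 0.656 and 0.857).

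Lysosomal genes rose mainly at the higher dose. Of 35 lysosome and autophagy genes 15 rose and 6 fell at 1 µg (camera adjusted p = 0.208) and 27 rose and 1 fell at 10 µg (the same adjusted over the list alone, median 0.56, camera adjusted p = 8.71e-07, adjusted p = 0.273 with an estimated correlation). The proton pump gene Atp6v0a1 gave 0.62 ± 0.06 and 1.16 ± 0.06. Energy metabolism leaned down. Of 63 nuclear oxidative phosphorylation genes 30 fell and 5 rose at 1 µg and 38 and 5 at 10 µg (the same adjusted over the list alone, camera adjusted p = 0.00256 and 0.0019, with adjusted p = 0.293 and 0.273 with an estimated correlation). Of 24 TCA cycle genes 15 fell at each dose and 4 and 3 rose (15 and 16 fell adjusted over the list alone, camera adjusted p = 0.0191 and 0.0265, with adjusted p = 0.429 and 0.495 with an estimated correlation). At 10 µg the TCA list had 0.05 without 10 µg 24 h replicate 1 and 0.0515 with library totals alone. Of 10 pentose phosphate genes 7 and 8 fell and 1 rose (8 and 8 fell adjusted over the list alone, camera adjusted p = 0.0156 and 0.0107, with adjusted p = 0.223 and 0.233 with an estimated correlation). Taldo1 gave -0.75 ± 0.05 and -0.93 ± 0.05. Glycolysis genes split 7 up and 10 down of 20 at 1 µg and 6 and 12 at 10 µg (camera adjusted p = 0.451 and 0.496). Of 13 mitochondrially encoded transcripts 1 rose and 3 fell at 1 µg (0 and 1 adjusted over the list alone) and 0 and 4 at 10 µg (camera adjusted p = 0.741 and 0.446). Of 16 iron-handling genes 3 rose and 9 fell at 1 µg and 6 and 7 at 10 µg (camera adjusted p = 0.089 and 0.838), with medians of -0.21 and -0.11 against means of 0.05 and 0.33. The iron uptake receptor gene Tfrc gave -1.85 ± 0.07 and -1.94 ± 0.07. At 1 µg this list had 0.035 without 1 µg 24 h replicate 1.

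Interferon-stimulated genes were lower at 24 h. Of 43 tested, 35 fell and 1 rose at 1 µg (median -0.51, camera adjusted p = 9.09e-08, adjusted p = 0.293 with an estimated correlation) and 38 fell and 2 rose at 10 µg (median -0.84, camera adjusted p = 2.51e-08, adjusted p = 0.273 with an estimated correlation), the same adjusted over the list alone. Ifit1 gave -1.70 ± 0.10 and -2.27 ± 0.11. Of 26 NF-kB genes 12 rose and 4 fell at 1 µg (camera adjusted p = 0.089) and 15 and 6 at 10 µg (camera adjusted p = 0.0454, adjusted p = 0.506 with an estimated correlation). Birc3 gave 0.86 ± 0.06 and 0.87 ± 0.06 and Tnfaip2 gave 0.83 ± 0.06 and 1.12 ± 0.06. The NF-kB list had 0.033 at 1 µg without 1 µg 24 h replicate 3, and at 10 µg 0.0501 and 0.053 without untreated replicates 2 and 3, 0.0523 with library totals alone and 0.0508 with the replicate block. Toll-like receptor primary response genes went 2 up and 4 down of 16 at 1 µg and 4 and 7 at 10 µg (camera adjusted p = 0.426 and 0.518). Secondary response genes went 1 up and 7 down of 13 and 3 and 7 (camera adjusted p = 0.0804 and 0.321). Without 1 µg 24 h replicate 1 these lists had 0.035 and 0.0215 at 1 µg, and the secondary list had 0.0286 with library totals alone. Of 9 chemokine genes 2 rose and 2 fell at 1 µg and 1 and 4 at 10 µg (camera adjusted p = 0.789 and 0.518). Cxcl2 gave 1.69 ± 0.41 and 1.77 ± 0.41, but at 1 µg 0.95 without 1 µg 24 h replicate 1 (adjusted p = 4.44e-07), and it missed with only the groups compared (0.0674). Ccl2 gave -1.95 ± 0.38 and -2.90 ± 0.45. Of 10 cytokine genes 5 rose and 0 fell at 1 µg and 6 and 1 at 10 µg (camera adjusted p = 0.105 and 0.139). Tnfsf9 gave 0.99 ± 0.06 and 0.90 ± 0.06.

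Marker lists of the M1 and M2 states gave no camera call at 24 h. Of 13 M1 markers 3 rose and 3 fell at 1 µg, where the median of 0.17 and the test's downward direction differed in sign, and 6 and 5 at 10 µg (camera adjusted p = 0.963 and 0.857). Irf5 gave -0.73 ± 0.05 and -0.93 ± 0.05. Of 13 M2 markers 6 rose and 2 fell at 1 µg and 8 and 0 at 10 µg (the same adjusted over the list alone, medians 0.66 and 0.75, camera adjusted p = 0.0814 and 0.0726). Clec7a gave 0.99 ± 0.06 and 1.23 ± 0.06 and Klf4 gave 2.48 ± 0.14 and 2.26 ± 0.14. Co-stimulatory and checkpoint ligands rose, 11 of 13 at 1 µg and 10 at 10 µg with 1 falling (the same adjusted over the list alone, medians 0.99 and 1.45, camera adjusted p = 0.00111 and 0.00362, with adjusted p = 0.223 and 0.24 with an estimated correlation). Cd83 gave 0.86 ± 0.06 and 1.45 ± 0.06 and the receptor gene Havcr2 gave -0.90 ± 0.07 and -1.04 ± 0.07. Of 22 negative regulators 8 rose and 9 fell at 1 µg, where the median was -0.12 and the mean 0.19, and 12 and 9 at 10 µg (camera adjusted p = 0.937 and 0.48). Immediate early genes went 7 up and 7 down of 22 at 1 µg, with a median of 0.01 and a mean of -0.04, and 9 and 10 at 10 µg (camera adjusted p = 0.886 and 0.883). Fos gave -0.83 ± 0.07 and -1.69 ± 0.08. Pattern recognition genes went 15 up and 11 down of 33 at 1 µg and 15 and 15 at 10 µg (camera adjusted p = 0.451 and 0.838). Of 14 inflammasome genes 7 rose and 1 fell at 1 µg and 9 and 1 at 10 µg (camera adjusted p = 0.0708 and 0.0637). That list had 0.0394 at 1 µg with library totals alone. Casp4 gave 1.06 ± 0.09 and 1.82 ± 0.09.

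Of 7 MHC class II genes 3 rose and 0 fell at 1 µg and 3 and 2 at 10 µg (camera adjusted p = 0.417 and 0.601). The invariant chain gene Cd74 gave 1.11 ± 0.07 and 1.12 ± 0.07. Of 22 class I processing genes 11 rose and 5 fell at 1 µg, where the median was 0.24 and the mean -0.27, and 12 and 7 at 10 µg (camera adjusted p = 0.261 and 0.496). Of 19 phagocytic and Fc receptor genes 8 rose and 3 fell at 1 µg and 10 and 4 at 10 µg (camera adjusted p = 0.0814 and 0.144). Fcgr2b gave 1.29 ± 0.05 and 1.47 ± 0.05. Homeostatic macrophage genes went 9 up and 6 down of 21 at 1 µg, with a median of -0.02 and a mean of 0.16, and 9 and 8 at 10 µg (camera adjusted p = 0.392 and 0.651). Of 18 osteoclast genes 4 rose and 7 fell at 1 µg and 8 and 6 at 10 µg, where the median was 0.21 and the mean -0.03 (camera adjusted p = 0.454 and 0.518). Nfatc1 gave -1.06 ± 0.06 and -1.44 ± 0.06. Matrix protease genes went 7 up and 5 down of 17 at 1 µg and 9 and 5 at 10 µg, with medians of 0.04 and 0.42 against means of -0.08 and -0.03 (camera adjusted p = 0.924 and 0.344). Complement and coagulation genes went 7 up and 5 down of 17 and 9 and 7 (camera adjusted p = 0.553 and 0.857), with C3 at 1.84 ± 0.13 and 2.15 ± 0.13.

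Genes kept as markers of other cell types also differed at 24 h. Of 9 dendritic cell markers 6 rose and 1 fell at 1 µg and 5 and 1 at 10 µg (camera adjusted p = 0.0804 and 0.144). Itgax gave 0.55 ± 0.08 and 1.45 ± 0.08. Both tested T cell markers rose at each dose, Cd28 by 1.87 ± 0.14 and 2.78 ± 0.14 and Lck by 0.83 ± 0.14 and 1.13 ± 0.14. Of 3 tested B cell markers 2 rose at each dose. The immunoglobulin gene Ighm rose from 1.13 to 11.3 CPM at 1 µg (3.31 ± 0.21) and to 3.68 CPM at 10 µg (1.69 ± 0.23), and Cd79a gave 1.73 ± 0.41 and 1.45 ± 0.43. Of 4 neutrophil markers 2 rose at each dose, Csf3r by 2.64 ± 0.13 and 3.19 ± 0.13, and at 10 µg 2 fell. The 1 tested fibroblast marker, Pdgfrb, rose at 1 µg (2.01 ± 0.49, and 1.32 without 1 µg 24 h replicate 1) and gave 0.33 ± 0.59 at 10 µg. The 1 tested epithelial marker, Ovol1, rose at 1 µg (1.70 ± 0.56) and gave 1.24 ± 0.60 at 10 µg, where it passed adjusted over the list alone and without 10 µg 24 h replicate 2 (0.0435). At 1 µg it missed without untreated replicate 1 (0.0545). For lists given at 24 h without such a count, the numbers adjusted over the list alone differed from those over all genes by at most 1 gene.

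**Figure D2:**
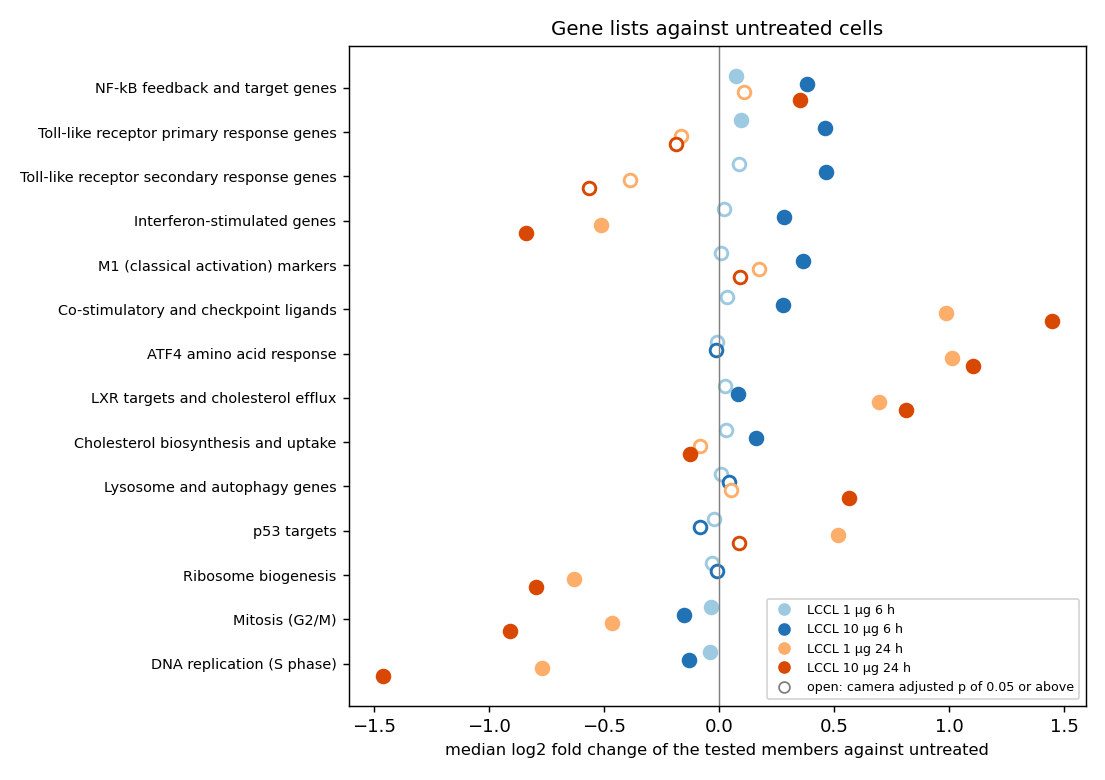
Median log2 fold change of the tested members of 14 gene lists in the 4 comparisons with untreated cells; filled points mark camera adjusted p under 0.05 with the preset correlation and open points the rest. DNA replication genes lie at -0.77 and -1.46 at 24 h, and NF-kB genes at 0.38 at 10 µg and 6 h.

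The comparison of 10 µg with 1 µg at 24 h tested the late dose difference. Atp6v0d2, a proton pump subunit gene, was higher at 10 µg (159.7 ± 7.43 against 44.9 ± 3.71 CPM, 1.83 ± 0.06, adjusted p = 1.4e-17). So were the deiodinase gene Dio2 (3.02 ± 0.25, adjusted p = 2.35e-09), Tspan10 (2.50 ± 0.21), the adhesion gene Sdk2 (2.03 ± 0.17) and Hal (1.97 ± 0.11). Cx3cr1, the fractalkine receptor gene, was lower at 112 ± 14.3 against 394 ± 84.7 CPM (3.52-fold, adjusted p = 7.51e-07). Also lower were the cyclin gene Ccne2 (-1.82 ± 0.17), which overlaps Ints8 on the other strand, and Itsn1 (-5.50 ± 0.71, adjusted p = 0.000108). Ranbp3l (-2.49 ± 0.59, adjusted p = 0.00723) and Ube2v1 (-4.17 ± 1.08, adjusted p = 0.012) varied widely at 1 µg, at 8.13 ± 7.6 and 7.67 ± 6.18 CPM, and did not pass when only the 2 groups were fitted (0.12 and 0.0733). Without 1 µg 24 h replicate 1 they gave -1.37 and -3.38, and without 10 µg 24 h replicate 1 Ube2v1 gave -4.94. Itsn1 gave -7.28 without 10 µg 24 h replicate 2. In all 4383 genes (35.3%) passed, 1988 higher and 2395 lower at 10 µg, of which 161 and 96 differed by at least 2-fold.

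Lysosomal genes separated the doses at 24 h, with 28 of 35 higher at 10 µg (median 0.43, camera adjusted p = 4e-15, adjusted p = 0.438 with an estimated correlation). Among them were the protease genes Ctsd (0.78 ± 0.06) and Ctsb (0.69 ± 0.06). DNA replication genes were lower, 45 of 47 (median -0.66, camera adjusted p = 5.18e-23), as were 48 of 51 mitosis genes (49 adjusted over the list alone, median -0.45, camera adjusted p = 2.62e-21), each with adjusted p = 0.438 with an estimated correlation. Interferon-stimulated genes were lower in 26 of 43 and higher in 3 (camera adjusted p = 3.2e-05, adjusted p = 0.787 with an estimated correlation). Ribosome biogenesis genes were lower in 23 of 37 (camera adjusted p = 3.18e-06, adjusted p = 0.633 with an estimated correlation). Smaller list shifts were those of ATF4 response genes (12 of 22 higher, camera adjusted p = 0.0268, adjusted p = 0.887 with an estimated correlation) and pentose phosphate genes (6 of 10 lower, camera adjusted p = 0.0213, adjusted p = 0.438 with an estimated correlation). Iron-handling genes (7 of 16 higher, camera adjusted p = 0.0218) and matrix proteases (7 of 17 higher, camera adjusted p = 0.0489) shifted too, both with adjusted p = 0.633 with an estimated correlation. The ATF4 list had 0.112 and 0.0776 without 1 µg 24 h replicate 1 and 10 µg 24 h replicate 3, and the iron list 0.144 without 1 µg 24 h replicate 3. The matrix list had 0.185 without 1 µg 24 h replicate 3 and 0.0967 and 0.0671 without 10 µg 24 h replicates 2 and 3, and 0.0581 with the replicate block. The NF-kB list was not called (0.153) but had 0.00983 without 1 µg 24 h replicate 1, and the cholesterol synthesis list (0.0984) had 0.00357 without 1 µg 24 h replicate 3.

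The comparisons of 24 h with 6 h at each dose used treated libraries alone, so the untreated libraries entered only through the shared spread. At 1 µg Trib3 was higher at 24 h by 4.31 ± 0.24 (adjusted p = 3.48e-08), Zrsr1 by 4.02 ± 0.65, Soat2 by 3.69 ± 0.10, Aldh1l2 by 3.48 ± 0.20 and Gdf15 by 3.32 ± 0.20. Zrsr1 gave 6.72 without 1 µg 6 h replicate 2. Pmepa1 (-5.31 ± 0.16, adjusted p = 2.85e-14), Id1 (-3.34 ± 0.13) and Gadd45g (-3.29 ± 0.18) were lower. At 10 µg Cp was higher at 24 h by 6.77 ± 0.48 (adjusted p = 3.67e-11), Cox6a2 by 6.18 ± 0.64, Trib3 by 5.51 ± 0.24, Extl1 by 5.40 ± 0.30 and Zrsr1 by 5.06 ± 0.69. Pmepa1 went from 113 to 1.42 CPM (-6.31 ± 0.16, adjusted p = 8.56e-16), and Itsn1 (-5.81 ± 0.69) and Olfml3 (-4.38 ± 0.20) were lower too. Without 10 µg 6 h replicate 2 Cp gave 10.32, without 10 µg 6 h replicate 1 Cox6a2 gave 7.28 and Zrsr1 4.45, and without 10 µg 24 h replicate 2 Itsn1 gave -7.59.

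At 1 µg 7533 genes differed between the times, 3756 higher and 3777 lower at 24 h, and with library totals alone the split was 4908 and 2794 (63.72% higher against 49.86%), with a shift of the median of 0.103. At 10 µg 8579 differed, 4218 higher and 4361 lower. DNA replication genes were lower at 24 h in 47 of 47 at each dose (camera adjusted p = 1.6e-16 and 3.58e-18, with adjusted p = 0.224 and 0.269 with an estimated correlation). ATF4 response genes were higher in 20 of 22 at each dose (camera adjusted p = 4.02e-11 and 3.62e-09, with adjusted p = 0.224 and 0.269 with an estimated correlation). Interferon-stimulated genes were lower in 36 and 41 of 43 (camera adjusted p = 2.32e-08 and 6.51e-12, with adjusted p = 0.286 and 0.269 with an estimated correlation). Toll-like receptor primary response genes were lower at 10 µg in 13 of 16 (camera adjusted p = 0.0063, adjusted p = 0.626 with an estimated correlation). Secondary response genes were lower in 8 and 9 of 13 (camera adjusted p = 0.0288 and 0.026, with adjusted p = 0.224 and 0.269 with an estimated correlation). In all 17 lists passed with the preset correlation at 1 µg and 15 at 10 µg.

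The interaction asked if the dose difference itself changed from 6 h to 24 h. Tspan10 (2.59 ± 0.44, adjusted p = 0.000196), Dio2 (2.12 ± 0.45, adjusted p = 0.00174), the GTPase gene Gbp8 (1.67 ± 0.43) and Creg2 (1.66 ± 0.43) gained on the lower dose by 24 h. Itsn1 (-4.69 ± 0.87), the cell fusion gene Ocstamp (-2.55 ± 0.35, adjusted p = 1.57e-05) and the heat shock gene Hspa1b (-2.10 ± 0.35) lost. Itsn1 gave -6.46 without 10 µg 24 h replicate 2, and Ocstamp -3.23 without 10 µg 24 h replicate 1. In all 2307 genes passed, 940 positive and 1367 negative. Lysosomal genes were positive in 27 of 35 (camera adjusted p = 6.36e-16). DNA replication genes (39 of 47, camera adjusted p = 3.26e-22), mitosis genes (39 of 51, camera adjusted p = 1.3e-15) and interferon-stimulated genes (31 of 43, camera adjusted p = 1.17e-15) were negative, and each of these 4 lists had adjusted p = 0.504 with an estimated correlation. Adjusted over the list alone these counts were 28, 43, 43 and 34. The primary response list was negative in 7 of 16 (8 adjusted over the list alone, camera adjusted p = 0.000497, adjusted p = 0.696 with an estimated correlation).

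Gorasp1 (2.15 ± 0.59, adjusted p = 0.0288), which overlaps Wdr48 on the other strand, Ranbp3l (-2.85 ± 0.79, adjusted p = 0.0308) and Slc5a3 (-2.05 ± 0.55, adjusted p = 0.0265), which overlaps Mrps6 on the same strand, also passed in the interaction. Without 1 µg 24 h replicate 1 Ranbp3l moved to -1.73 (adjusted p = 1.39e-05) and Slc5a3 to -1.31 (adjusted p = 0.00202), and without 1 µg 6 h replicate 3 Gorasp1 moved to 1.52. Fitted with only the 4 treated groups they had 0.055, 0.0605 and 0.0541. Gorasp1 had 0.0665 without 1 µg 6 h replicate 3, 0.0735 and 0.0706 without 10 µg 6 h replicates 1 and 3, and 0.0541 and 0.0572 without 10 µg 24 h replicates 2 and 3. Ranbp3l had 0.0558, 0.0662 and 0.0607 without 1 µg 6 h replicates 1, 2 and 3, 0.0597, 0.0591 and 0.0532 without 10 µg 6 h replicates 1, 2 and 3, and 0.0544, 0.0703 and 0.0727 without 10 µg 24 h replicates 1, 2 and 3. Slc5a3 had 0.06 and 0.0575 without 1 µg 6 h replicates 1 and 3, 0.0525 and 0.0554 without 10 µg 6 h replicates 1 and 2, and 0.0624 and 0.069 without 10 µg 24 h replicates 2 and 3.

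The comparisons with untreated cells shared their control libraries, which alone makes fold changes correlate. Both doses at 24 h called 3307 genes higher and 3414 lower, against 1351 and 1341 for independent calls, and 40 rose at 1 µg and fell at 10 µg while 52 did the reverse, against 1332 and 1359. Across genes, which are not independent replicates, the log2 fold changes at 24 h had a covariance of 0.511 between doses, where 20 simulations with shared controls and no other effect gave 0.0122 on average. For 10 µg at 6 h and 24 h the covariance was 0.0487 against 0.0121, with 293 genes higher at both times, 145 lower at both, 144 higher and then lower, and 48 lower and then higher, against 179, 81, 177 and 82 for independent calls. The correlation of that pair was 0.199, under the 0.495 of the simulations, and that of the doses at 24 h was 0.88 against 0.502.

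**Figure D3:**
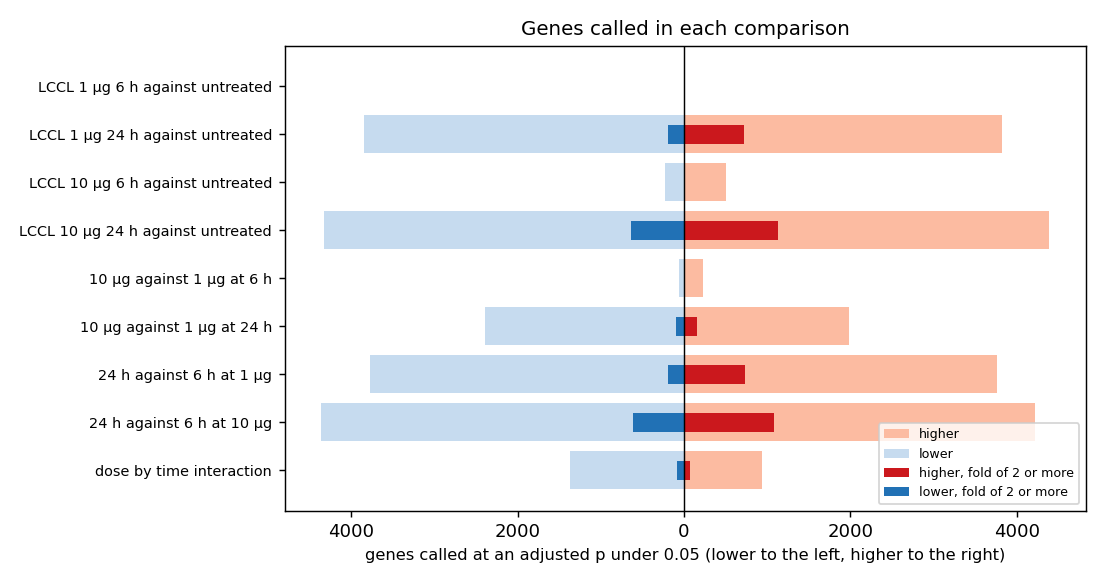
Genes with an edgeR adjusted p under 0.05 in the 9 comparisons, higher to the right and lower to the left, with the darker part of each bar for changes of at least 2-fold. The bars run from 0 genes at 1 µg and 6 h to 8717 at 10 µg and 24 h.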

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

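The tests of time in culture, scaling, overlapping genes, a switch of transcription, endotoxin, RNA from other cells and the balance and mixing of times within splits were chosen after the results were seen; the splits themselves were planned.

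Expression differed between 24 h and 6 h in 7533 genes at 1 µg and 8579 genes at 10 µg. These counts contain any effect of time in culture, as no untreated libraries are labelled with either time. The dose difference itself differed between the times in 2307 genes, and in that contrast an effect of time that is equal at both doses cancels. Among single genes the interaction was 2.59 for Tspan10, 2.15 for Gorasp1, 2.12 for Dio2, 1.67 for Gbp8 and 1.66 for Creg2 on the log2 scale, and -4.69 for Itsn1, -2.85 for Ranbp3l, -2.55 for Ocstamp, -2.10 for Hspa1b and -2.05 for Slc5a3. Among lists the median interaction was -0.21 for NF-kB genes, -0.51 for interferon-stimulated genes, -0.21 for cholesterol synthesis genes, 0.16 for ATF4 response genes, 0.39 for lysosome genes, -0.58 for DNA replication genes, -0.37 for mitosis genes, -0.20 for ribosome biogenesis genes, 0.23 for iron-handling genes and -0.37 for Toll-like receptor primary response genes. These list calls rest on the preset correlation and had adjusted p from 0.504 to 0.75 with an estimated correlation. Without single libraries the ATF4 list had 0.0892 (1 µg 24 h replicate 1), the iron list 0.0654 (1 µg 24 h replicate 3) and the NF-kB list 0.0787 (10 µg 24 h replicate 1), and Gorasp1, Ranbp3l and Slc5a3 lost their calls in some such fits, with adjusted p up to 0.0735, 0.0727 and 0.069. Without 1 µg 24 h replicate 1 Ranbp3l and Slc5a3 moved to -1.73 and -1.31, without 1 µg 6 h replicate 3 Gorasp1 moved to 1.52, without 10 µg 24 h replicate 2 Itsn1 moved to -6.46 and without replicate 1 Ocstamp moved to -3.23.

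Splits of the libraries were counted for each comparison. For the interaction 3 of 100 splits, the real one included, gave as many genes, a share under 0.05 that was the bound set in advance. That bound was wrong for these splits: each of the 99 others mixed the times within groups, so that the time effect entered the spread, and 94 of them called 0 genes. They say nothing on chance for the interaction. The highest other splits called 5832 and 5229 genes, more than the real 2307, which points to a structure of the samples. Both held 5 of the 6 libraries of 24 h on the same side of the contrast, so the difference between times entered it. The first principal component of the libraries held 65.98% of the variance. On it the 24 h libraries lay from 29.08 to 58.44 and all others from -30.88 to -27.5. The 6 splits with 5 libraries of 24 h on the same side still called from 0 to 5832 genes, and why they differed was not tested. For the other comparisons only 10 splits exist, too few for a share under 0.05. Each split but the real one mixed libraries of both groups on each side, so that a difference between the groups entered the spread. Few or no calls were bound to follow there, and the counts below say nothing on chance. The real split called 7658, 738, 8717, 291, 7533 and 8579 genes in the 1 µg 24 h, 10 µg 6 h, 10 µg 24 h, 6 h dose and both time comparisons, where the highest other split called 0, and 4383 in the 24 h dose comparison, where the highest other called 1. In each of these 7 comparisons 1 of 10 splits gave as many genes, the real one. At 1 µg and 6 h the real split called 0, as did all 10 splits.

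Most genes differed between 24 h of treatment and the untreated cells, and time in culture is an explanation that the design leaves open in part. As the whole cause at 10 µg it is argued against by the 4383 genes that differed between the doses at 24 h. Of 3205 genes called both at 1 µg 24 h against untreated and between the doses, 2537 (79.2%) moved further the same way at 10 µg. The other 668 moved back. As the doses share the 24 h, this argues against time as the whole cause at 10 µg for these genes. For the 6721 genes called the same way at both doses, the part common to both remains open. Effects of the peptide and of time in culture cannot be told apart there, since the labels give no harvest time for the untreated cells. With library totals in place of TMM scaling, 87.2% of the calls at 1 µg and 24 h (6681 of 7658) kept both their call and their direction. The rest lost their call. The change of scaling moved the median by only 0.102, under the median called change of 0.421, so most calls were bound to hold. Both scalings are relative, so a change in the total RNA per cell cannot be seen. Scaling as a cause stays open in that respect.

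Some genes switched between 0 counts in every library of a group and over 100 counts in another group: 14 genes, with Exosc6 and Yy2 among them. Reads shared with an overlapping gene may explain most of them, as 76.9% of the 13 that could be looked up had an exon overlapping another gene's exon, against 38.5% of 12098 tested genes (Fisher's exact test, two-sided, p = 0.00745). On the same strand the shares were 53.8% and 9.53% (Fisher's exact test, two-sided, p = 7.18e-05). For the 3 switching genes without an overlapping exon, a switch of transcription and a fault of the counting cannot be told apart, because the strand setting and annotation behind the counts are not given in the sources used here.

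NF-kB and Toll-like receptor response genes rose at 10 µg and 6 h, and endotoxin carried in the peptide preparation may produce the same pattern. Of 13 tested Toll-like receptor secondary response genes 7 rose, which either the peptide or endotoxin could give. These cannot be told apart without a vehicle or endotoxin control. The labels name RAW264.7 cells alone as the source, but RNA of other cell types was not excluded by the markers tested. Of the 11 tested markers, of 64, of fibroblasts, epithelium, T cells, B cells and neutrophils 0% were higher, a share under the bound first set against it. But the most abundant, Fcrla, stood at only 5.96 CPM against 7.02 CPM in untreated cells, and the lowest, Ovol1, at 0.161 CPM. So few markers at such low levels do not decide the question. The 64 leave out dendritic cells, of whose 9 tested markers 2 were higher, Cd83 (0.62 ± 0.06) and Itgax (0.35 ± 0.09, and adjusted p = 0.0913 and 0.0577 without untreated replicate 1 and 10 µg 6 h replicate 3). The list had camera adjusted p = 0.0514, and 0.0439 and 0.0378 with DESeq2 size factors and library totals alone. Between the doses at 6 h that list had camera adjusted p = 0.0328, and adjusted p = 0.23 with an estimated correlation.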

How the results depend on the processing

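None of the alternatives was added after the results were seen, and none turned the sign of a called change of a named gene. Which direction held more genes did turn where the counts were near even. For example, 10 µg 24 h had 4199 higher and 4255 lower with DESeq2, 1 µg 24 h had 3551 and 3256 at the 5 CPM filter, and 24 h against 6 h at 10 µg had 5132 and 3544 with library totals alone. Of the values of named genes under alternatives 1938 stayed on their side of the threshold, 101 lost a call and 5 gained 1. Counts of called genes stayed within 1.5-fold under DESeq2, limma-voom, both other scalings, the 5 CPM filter, thinning and the replicate block, with these exceptions: without a filter the count at 1 µg and 6 h was 1 in place of 0, and with only the groups compared it was 1487 in place of 738 at 10 µg and 6 h and 1044 in place of 291 between the doses at 6 h. In those smaller fits the spread is estimated from fewer libraries and without the 24 h groups. The mean squared difference between libraries of a group, over that from counting error, was 4.532 to 15.03 in the 24 h groups. It was 2.526 to 4.973 in the other groups. Whether this is the cause was not tested. With the replicate number as a block the counts were 7601 at 1 µg 24 h, 708 at 10 µg 6 h and 8630 at 10 µg 24 h. The labels do not say if samples with the same number belong together. Their 30 correlations ran from -0.0814 to 0.0963, and in 15 of these the library of the same number was the closest in its group. Pairing was therefore not seen clearly, but it is not excluded.

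Leaving out 1 library at a time gave 390 to 469 genes at 10 µg and 6 h and 111 to 163 between the doses at 6 h, each below its full count whichever library was left out. The other counts stayed within 1.5-fold: 7016 to 7391 at 1 µg 24 h, 8242 to 8411 at 10 µg 24 h, 3581 to 4458 between the doses at 24 h and 1764 to 2723 for the interaction. At 1 µg and 6 h it was 0 in each fit. Fewer replicates leave fewer degrees of freedom. Only libraries of the groups compared were left out, so the 24 h libraries stayed in these fits for the 6 h groups.

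With the replicate block 17 of 20 list calls at 10 µg 6 h, 14 of 15 at 10 µg 24 h, 17 of 19 and 8 of 9 between the doses at 6 h and 24 h and 16 of 17 between the times at 1 µg were kept. With library totals alone 12 of 15 at 10 µg 24 h, 18 of 19 between the doses at 6 h and 14 of 17 and 14 of 15 between the times were kept. The number of lists called at 1 µg and 6 h ran from 1 to 8 without single libraries, against 5. Leave-one-out fits ended calls of 4 of the 5 lists at 1 µg 6 h, 0 of 14 at 1 µg 24 h, 8 of 20 at 10 µg 6 h, 3 of 15 at 10 µg 24 h, 5 of 19 between the doses at 6 h, 3 of 9 at 24 h, 3 of 17 and 1 of 15 between the times at 1 µg and 10 µg, and 3 of 10 in the interaction. With an estimated correlation 2 lists were called at 10 µg 6 h and 2 between the doses at 6 h, and 0 in each of the other 7 comparisons. The rotation test fry called 0 lists at 1 µg 6 h, 32 at 1 µg 24 h, 20 at 10 µg 6 h, 35 at 10 µg 24 h, 13 and 21 between the doses at 6 h and 24 h, 34 between the times at each dose and 14 in the interaction. It kept 0 of 5 list calls at 1 µg 6 h, 17 of 20 at 10 µg 6 h, 12 of 19 between the doses at 6 h and 9 of 10 in the interaction, and each call in the other 5 comparisons. It does not set a list against other genes.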

Other observations

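The hypothesis of lower SMAD signalling was written with its test before its values were computed, although Junb and Tgfbr1 had been seen in other lists; a bound in it was changed afterwards.

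Id1, Id2, Id3, Smad6 and Pmepa1, which SMAD factors induce, were among the genes lower at 24 h, and a lower SMAD signal is a candidate explanation. With the targets of the largest falls left out, which can pull a median toward 0, it was tested on 17 other SMAD targets. At 1 µg their median log2 fold change was -0.111, with 6 rising and 8 falling (camera p = 0.501, 0.619 with an estimated correlation), and at 10 µg it was 0.000301, with 7 rising and 7 falling (camera p = 0.956, 0.967 with an estimated correlation). The value at 10 µg met the bound set in advance against the hypothesis (0 or above), but a median near 0 over members that go both ways decides nothing, so the bound was changed to need a median above its own SE and the question stays open at both doses. Smad7 (-1.98 ± 0.16), Rgcc (-1.52 ± 0.29) and Skil (-1.25 ± 0.06) fell furthest at 1 µg, as the hypothesis asks. Of the 6 that rose there, Ldlrad4 went furthest (0.94 ± 0.10), and Tgif1 was another (0.35 ± 0.05).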
